A study of Mus musculus with 6 samples.

How the data were processed

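The series examined where the transcription factor Fezf2 binds DNA in mouse cortical progenitors. Progenitors from embryonic day 14.5 brains of the CD1 strain were expanded as neurospheres, which are floating clusters of neural stem cells, and then plated as a monolayer. They were infected with a virus carrying Fezf2 with a triple Flag tag, or the tag and a green fluorescent protein without Fezf2, or were left uninfected as a mock control. The sample titles call the infected samples induced and the mock samples uninduced. Chromatin of infected cells was collected 48 hours after infection, sheared to between 200 and 700 bp and precipitated with an antibody against Flag, per the labels' protocols. The 6 samples fall into 3 groups of 2. Processed files of the 2 Fezf2-3Flag samples were analysed; files of the GFP-3Flag and mock samples were not analysed here. The series design calls the duplicates biological.

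Each Fezf2-3Flag replicate had its own list of binding events, so the authors called events per replicate and not on pooled reads. The version and settings of the caller, and the control library behind each list, are not given in the sources used here. Base calling with CASAVA 1.4, alignment with Bowtie 0.12.7 and the genome build mm9 are named in the submitters' processing notes. An event is listed at a single base. Per the file headers, the read signal of each event comes in 3 deposited columns, which are the reads of the immunoprecipitation (IP), the reads of the control and the expected reads. IP reads were not always whole numbers: 65.8% of values equalled their nearest whole number in replicate 1 and 57.0% in replicate 2. Whether control reads were scaled to the IP library is not stated. The deposited fold is the linear ratio of IP to control reads. It is set to a fixed high value at the 28 events of replicate 1 with no control reads. The deposited significance is a −log10 of p or q, and every event had a −log10 q of 3 or more, so no event listed by the authors had a q above 0.001. The −log10 p is capped at 15.95, a value held by 36.2% of events of replicate 1 and 47.0% of replicate 2. Further deposited score columns, per the file headers, compare the read profile with a model or the control, and rate the k-mer group of the event. A k-mer is a short sequence that the deposited table assigns to an event, and each list had its own set. The column for longer bound sequences was empty in every row. The second file of each replicate held the same positions and the whole part of the same read signal in every row as deposited.

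The total number of reads per library is not in these lists, so sequencing depth is unknown and values were compared mainly by rank and by position. The summed reads of listed events are not the depth. Intervals are 95% Wilson intervals for shares and exact Poisson intervals for densities, and cover counting error only. Sites are not independent replicates, so p-values over sites describe these 2 lists.

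Positions are those of the deposited tables, in mm9. The companion files give the same number as a start coordinate, which leaves an uncertainty of 1 bp. The gene table at hand is for GRCm38.p6, and no coordinates were converted between builds. For this reason no event was assigned to a gene, and the planned share of events near start sites and the tests of 12 gene lists were not run.

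Events of replicate 1 within 100 bp of an event of replicate 2 were called shared. Chance was set by shifting the events of replicate 2 along each chromosome, end joined to start, 1000 times at 100 bp and 200 times at other distances. The chromosome end was the last event of either list. Paired events were each other's nearest within 100 bp. Regions were made by joining events of a list at most 1000 bp apart. Strength was compared with Spearman's and Pearson's correlation of log2 IP reads and 100000 permutations, two-sided. Events were ranked within their list by IP minus control reads and divided into 10 equal bins. Median folds were compared with 100000 permutations of the shared label, two-sided, and shares with Fisher's exact test, two-sided. The share of paired events with matching k-mers was set against 1000 shuffles of the k-mers over the pairs. These 9 tests formed 1 family for the Benjamini-Hochberg adjustment, which the later correlation over chromosomes did not enter. A k-mer of replicate 1 matched one of replicate 2 if it, or its reverse complement, lay inside it. The lists of alternatives, the tests, the string and the rule for named items were fixed before the data were examined, except those said here to be added later. The named items are the 10 paired events with the smallest value of the larger of their ranks in the lists, and the 5 most frequent k-mers of each list. A string, AAGAGC, was fixed in advance from general knowledge of zinc fingers of the Fez family and compared with the rearrangements of its letters. Event density per chromosome and the k-mer cores were added after seeing the data.

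Alternatives were other overlap distances, stricter lists (−log10 q of at least 5, or a fold of at least 5), other rankings, other strings and single lists. The overlap and permutation code was tested on simulated data with 27169 positions of replicate 1. Of 5000 planted pairs with offsets of 30 bp SD, 99.9% were recovered, and 0 of 40 unrelated simulated lists gave p under 0.05. The planted offsets were narrower than the real ones (median absolute offset 102 bp among pairs within 500 bp). The unrelated lists were drawn evenly along each chromosome, without the clustering of real events. These runs therefore check the code and not its behaviour on lists like the real ones. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.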

Results

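Binding of Flag-tagged Fezf2, a zinc finger transcription factor that specifies subcortical projection neurons of the cerebral cortex, was profiled by ChIP-seq in neurosphere-derived cortical progenitors. Replicate 1 held 27169 binding events and replicate 2 held 20687. Events of replicate 1 carried a median of 58.5 IP reads (interquartile range 35 to 95) and of replicate 2 a median of 127.7 (97 to 181). The weakest listed event had 20.0 IP reads in replicate 1 and 76.0 in replicate 2. Median control reads at events were 3.5 in replicate 1 and 25.9 in replicate 2. The median fold of IP over control was 18.2 (11.7 to 28.1) in replicate 1 and 5.3 (3.9 to 7.4) in replicate 2. The total depth of the libraries is unknown, so read numbers were not set against each other as levels of binding.

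The first comparison asked which Fezf2 sites were found in both replicates. Within 100 bp, 7189 events of replicate 1 had a partner in replicate 2, which was 26.5% of its list (95% Wilson interval 25.9 to 27.0). Seen from replicate 2, 7194 events were shared, or 34.8% (34.1 to 35.4). Shifting one list along the chromosomes left a mean of 46.5 shared events and at most 68, so the observed number was 155 times chance (one-sided permutation p = 0.001, the smallest that 1000 shifts can give; adjusted p = 0.001). With local shifts of 5 to 50 kb, a setting chosen after seeing the data, the mean was 122 and the observed number 58.8 times chance. The shifts place events regardless of sequence, so any lists that favour the same kind of site would exceed them. No GFP-3Flag or mock list was compared, so the overlap does not separate Fezf2 binding from other enrichment common to the replicates. The number shared depended on the distance allowed. At 500 bp, 15764 events of replicate 1 (58.0%, interval 57.4 to 58.6) and 15666 of replicate 2 (75.7%, 75.1 to 76.3) had a partner, against means of 218 and 222 by chance. At 50 bp, 4445 events of replicate 1 did, and 4597 did at 100 bp when only events of at least 5-fold over control were kept.

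Most binding regions of replicate 2 lay near a region of replicate 1, although the called base often differed by more than 100 bp. Joining events at most 1000 bp apart gave 23683 regions in replicate 1 and 18362 in replicate 2. Of these, 59.3% (interval 58.7 to 59.97) and 77.3% (76.7 to 77.9) had a region of the other replicate within 1000 bp. More than 1 event lay in 13.8% of regions of replicate 1 and 12.2% of replicate 2, with at most 4 events in a region. Among the 14536 mutually nearest events within 500 bp, the median absolute offset was 102 bp, which is below the shortest sheared fragment of 200 bp, and the median signed offset was 1 bp. Offsets were concentrated near 0: 49.4% lay within 100 bp, where evenly spread offsets would place 20.1%.

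**Figure D1:**
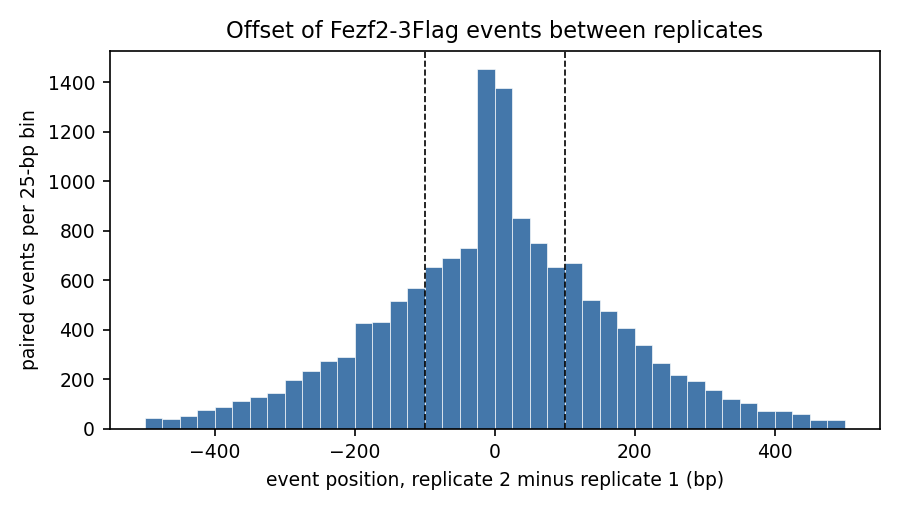
Histogram of the offset between mutually nearest Fezf2-3Flag events, replicate 2 minus replicate 1 in bp, in bins of 25 bp; dashed lines mark 100 bp on either side. The 2 bins beside 0 hold 1454 and 1377 pairs and the outermost bins 44 and 35.

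Stronger sites were shared more often. The share of replicate 1 events with a partner within 100 bp was 6.33% (interval 5.48 to 7.31) in the weakest of 10 equal bins of the list and 47.5% (45.6 to 49.4) in the strongest. In replicate 2 it went from 19.9% (18.2 to 21.6) to 45.1% (43.0 to 47.3). Both differences passed Fisher's exact test between these bins (two-sided; p = 1.4e-281, adjusted 1.3e-280, for replicate 1 and p = 1.5e-68, adjusted 4.6e-68, for replicate 2). Within 500 bp, 94.9% (94.0 to 95.7) of the strongest bin of replicate 1 and 93.8% (92.7 to 94.8) of replicate 2 had a partner. Ranked by fold in place of IP minus control reads, the difference between the outer bins fell from 41.2 to 8.58 percentage points in replicate 1. In replicate 2 it was 20.4 points by fold, beside 25.3.

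**Figure D2:**
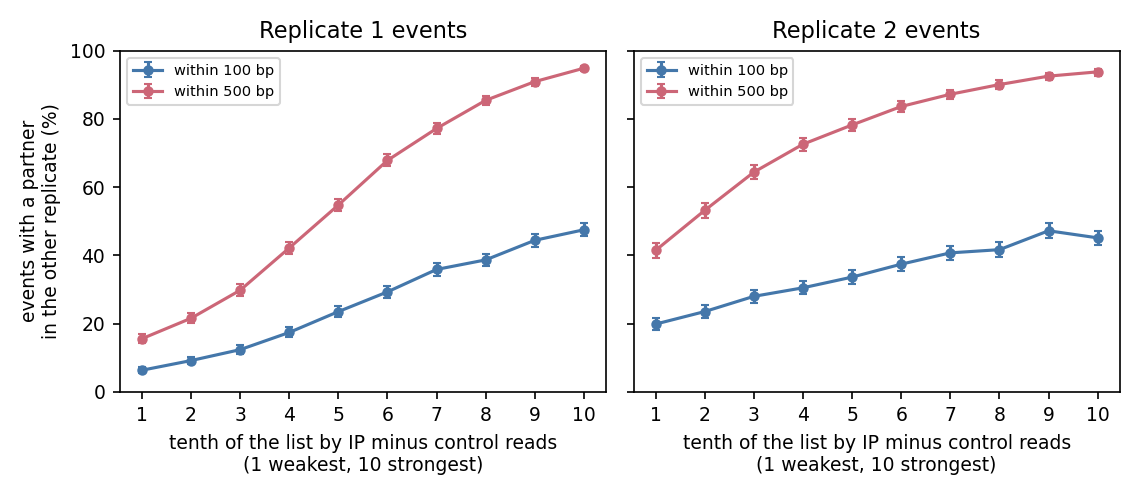
Percent of events with a partner in the other replicate, in 10 equal bins of each list ranked on IP minus control reads (1 weakest, 10 strongest), within 100 bp and within 500 bp, for replicate 1 (left) and replicate 2 (right); points are shares and bars 95% Wilson intervals. Within 500 bp the share climbs from 15.6% to 94.9% in replicate 1 and from 41.5% to 93.8% in replicate 2.

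Read numbers at the same site went together in the replicates. Over 7187 paired events, Spearman's rho of IP reads was 0.56 and Pearson's r of log2 IP reads was 0.58 (two-sided permutation p = 1e-05 for each, the smallest that 100000 permutations can give; adjusted p = 1.3e-05 for rho). The median ratio of replicate 2 to replicate 1 was 1.77. These values are across sites, which are not independent replicates. On the deposited folds in place of reads, rho was 0.34. Shared events also stood higher over the control than unshared ones: the median fold was 20.5 against 17.4 in replicate 1 and 5.8 against 5.0 in replicate 2 (two-sided permutation test, p = 1e-05 and adjusted p = 1.3e-05 in each). The difference of medians was 3.1 in replicate 1 and 0.80 in replicate 2. With sharing defined at 500 bp it was 5.3 and 2.1.

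**Figure D3:**
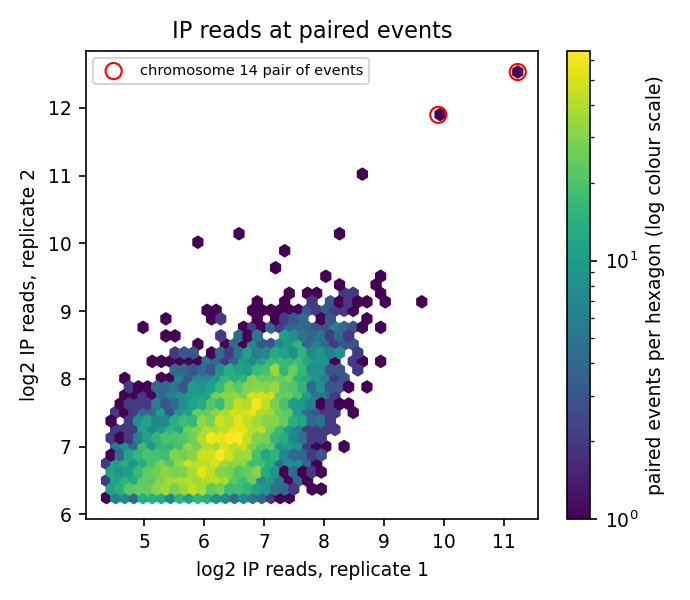
Log2 IP reads of 7187 paired events in replicate 1 (x axis) and replicate 2 (y axis); hexagon colour gives the number of events on a log scale, and circles mark the 2 strongest pairs, both on chromosome 14. The cloud slopes upward (Spearman's rho 0.56), with the circled pairs apart from it.

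The strongest Fezf2-3Flag signal in both replicates lay at one place on chromosome 14 (positions in mm9). The first event was at position 13177392 in replicate 1 and 13177367 in replicate 2, with 2403.8 and 5913.6 IP reads, 189.7-fold and 491.9-fold over control. The second was at position 13177048 in replicate 1 and 13176996 in replicate 2, with 959.2 and 3815.7 IP reads, 101.8-fold and 278.5-fold over control. Control reads there were 12.7 and 9.4 in replicate 1 and 12.0 and 13.7 in replicate 2. In replicate 2 a further event, at position 13175171, had 1554.7 IP reads, and its nearest event of replicate 1 was 1877 bp away. The IP reads of replicate 2 were 2.46 times those of replicate 1 at the first event and 3.98 times at the second, beside a median of 1.77 over the other pairs. The first event had 3.00 times the IP reads of the strongest event elsewhere in the genome in replicate 1, and 2.90 times in replicate 2. Binding at this place and reads from the infected Fezf2 construct could not be told apart here.

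The other 8 named pairs lay on 7 chromosomes. A site on chromosome 10 at position 36857062 (36856994 in replicate 2) had 509.2 and 704.9 IP reads, 58.1-fold and 18.9-fold over control. Another on chromosome 14, at position 26278805 (26278800 in replicate 2), had 452.2 and 671.8 IP reads, 71.1-fold and 19.1-fold over control. A site on chromosome 3 at position 90237444 (90237532 in replicate 2) had 425.0 and 585.0 IP reads, and one on chromosome 7 at position 80763507 (80763506 in replicate 2) had 368.3 and 597.4. A further site on chromosome 14, at position 106296696 (106296700 in replicate 2), had 483.1 and 620.4 IP reads. The sites on chromosome 1 at position 88384082 and on chromosome 4 at position 135841904 had 365.0 and 505.0 IP reads in replicate 1 and 613.0 and 552.3 in replicate 2. The remaining one, on chromosome 11 at position 108873229 (108873215 in replicate 2), had 419.0 and 2037.0 IP reads. Its control was high as well, at 29.5 and 621.4 reads, so its fold was 14.2 in replicate 1 and 3.3 in replicate 2. No gene was assigned to any of these positions, because the gene table used here is of another build.

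The sequences assigned to events were rich in G and C in both replicates. A k-mer was assigned to 85.1% of events of replicate 1 (interval 84.7 to 85.5) and 71.8% of replicate 2 (71.2 to 72.4), a mean of 78.5% ± 9.38 (SD, n = 2). All 26 k-mers of 7 bases in replicate 1 and all 60 of 8 bases in replicate 2 held a CG dinucleotide, which in vertebrate genomes is concentrated in CpG islands. G and C made up 92.9% of the bases of assigned k-mers in replicate 1 and 89.5% in replicate 2. Events with a k-mer had more IP reads than those without, with medians of 63.7 against 36.8 in replicate 1 and 139.8 against 105.0 in replicate 2. Control reads did not go up with them: the medians were 3.5 for each in replicate 1, and 25 with and 27.7 without a k-mer in replicate 2.

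The leading sequences of replicate 1 were CCGCCGC with 4918 events, CGCCGCC with 3104, GCGCCGC with 2206, CCGCTGC with 1962 and GCGCTGC with 1639. Those of replicate 2 were GGCGGGGC with 3337 events, GGAGGCGG with 1328, GGGCGGAG with 1309, GGCGGCGC with 896 and AGGGGGCG with 574. These 5 made up 59.8% of events with a k-mer in replicate 1 and 50.1% in replicate 2. The core GGCGG, on either strand, lay in the k-mers of 40.5% of such events in replicate 1 and 78.8% in replicate 2. The exact string GGGCGG, the core of the GC box bound by factors of the Sp1 family, lay in 18.9% of them in replicate 2 and in none of the k-mers of replicate 1. This share leaves out the leading k-mer GGCGGGGC (22.5%), which does not hold the whole string. Of the 26 k-mers of replicate 1, 8 lay inside a k-mer of replicate 2. Both replicates had a k-mer at 5878 paired events, and at 15.5% of these (interval 14.6 to 16.5) the k-mers matched, against 5.10% after shuffling (one-sided permutation p = 0.001, the smallest that 1000 shuffles can give; adjusted p = 0.001). At most 22.0% could have matched under any pairing of their k-mers. Paired events lie on nearly the same sequence, so an excess over shuffled pairs follows in part from position alone. The cores were chosen after seeing the k-mers. A k-mer of 8 bases has more room for a core than one of 7, so the shares with a core are not directly comparable between the replicates.

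Shared sites carried a k-mer more often than unshared ones. The shares were 89.2% and 83.6% in replicate 1 (two-sided Fisher's exact test, p = 2.8e-31, adjusted 6.3e-31) and 85.9% and 64.3% in replicate 2 (p = 9.2e-257, adjusted 4.1e-256). With sharing defined at 500 bp, the difference was 12.6 percentage points in replicate 1 in place of 5.55, and 55.3 in replicate 2 in place of 21.6. With only events of at least 5-fold over control, it was 9.52 points in replicate 1 and 10.9 in replicate 2. The share of events with a k-mer also rose with strength, from 67.6% in the weakest bin of replicate 1 to 95.8% in the strongest. In replicate 2 it rose from 44.1% to 89.1%. Stronger events were shared more often, and strength was not held fixed here, so the comparison does not separate sharing from strength. The share of sites in both lists varied with the k-mer, which was not tested. In replicate 2, 66.6% of events with GGCGGCGC (interval 63.5 to 69.6) and 29.1% with AGGGGGCG (25.5 to 32.9) were shared within 100 bp. In replicate 1, 39.9% with CGCCGCC (38.2 to 41.7) and 20.4% with CCGCTGC (18.7 to 22.2) were. The string AAGAGC, fixed in advance, was in 0 of 23116 k-mers assigned in replicate 1 and 0 of 14857 in replicate 2. Of the 60 arrangements of its letters, 0 were in any k-mer of replicate 1 and 2 in replicate 2, so its absence did not set it apart from them.

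Event density along the genome ranked the chromosomes in a similar order in both replicates. Among the autosomes and X, chromosome 11, which is rich in genes, was the densest with 20.4 events per Mb in replicate 1 (exact Poisson interval 19.6 to 21.3) and 14.3 in replicate 2 (13.7 to 15.0). Chromosome 19 followed with 15.9 (14.8 to 16.9) and 12.3 (11.4 to 13.2). Chromosome X was the sparsest of these 20, with 3.47 (3.19 to 3.77) and 1.81 (1.60 to 2.03). The median autosome had 11.6 events per Mb in replicate 1 and 8.33 in replicate 2, so X stood at 0.30 and 0.22 of it. Over the 20 chromosomes, Pearson's r of the densities was 0.97 and Spearman's rho 0.97 (two-sided permutation p = 1e-05 each, the smallest that 100000 permutations can give). Without chromosomes 11 and X, r was 0.96. Densities are per Mb between the first and the last event of either list, and chromosomes are not independent replicates. At events on X, IP reads, control reads and fold had medians of 46.0, 2.2 and 21.0 in replicate 1, against 59.0, 3.5 and 18.2 on autosomes. In replicate 2 they were 107.9, 17.6 and 6.5, against 128, 25.9 and 5.3.

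**Figure D4:**
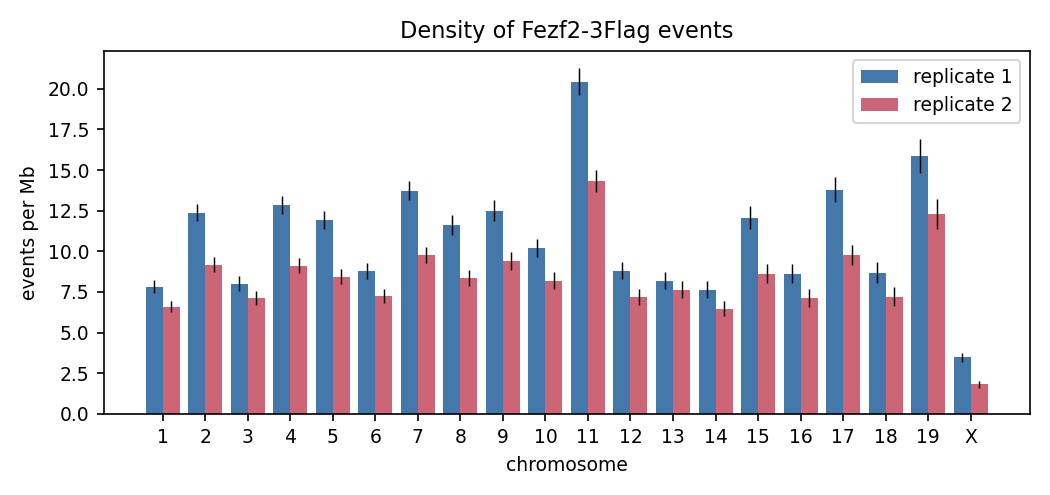
Fezf2-3Flag events per Mb on each autosome and on X in replicate 1 and replicate 2; bars are densities and lines exact 95% Poisson intervals. Of the 20 chromosomes drawn, chromosome 11 is highest, at 20.4 and 14.3, and chromosome X lowest, at 3.47 and 1.81.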

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

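No test was run on the events named here, which were singled out after the lists were seen because they lie outside the chromosomes compared. Events were also listed on contigs not placed within a chromosome, which the densities per chromosome leave out: 20 in replicate 1 and 16 in replicate 2. They stood 3.5-fold to 81.6-fold over control in replicate 1 and 2.5-fold to 15.8-fold in replicate 2, and 13 in each list had a partner within 500 bp. Chromosome Y held 1 event, at position 346988 in replicate 2, with 95 IP reads, 9.2 control reads and a fold of 10.3.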

How the results depend on the processing

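Settings chosen only after seeing the data were the 10000 strongest events, the lists without the chromosome 14 pairs, those without events of high control reads, local shifts, and the share of events with a k-mer in single lists. Of 42 alternatives, 4 were counted as having an outcome fixed by construction (single lists for the share of events with a k-mer and for a string at 0 events). Of the other 38, 32 kept the direction and the side of the threshold, or stayed within 1.5 times of a count or within 1 SD of the share of events with a k-mer. None of the 38 changed a direction or lost a test. The 32 include the string AAAGAGC, which holds AAGAGC and so had to be at 0 events too. They also include counts of shared events with little room to move. These left out the chromosome 14 pairs or chromosomes X, Y and M, or counted from replicate 2. The 7189 shared events of replicate 1 became 4445 at 50 bp, 12640 at 250 bp and 15764 at 500 bp. They became 4597 with a fold of at least 5, where replicate 2 kept 11488 events, and 3216 among the 10000 strongest events of each list, where fewer events were compared. Each exceeded all 200 shifts (one-sided permutation p = 0.005, the smallest they can give). The mean share of events with a k-mer, 78.5%, became 89.2% among the 10000 strongest events (the cause was not tested) and lay between 71.8% and 85.1% in single lists. Matching k-mers stayed between 15.5% and 15.6%. The other strings tried in place of AAGAGC also had 0 events. The overlap needs both lists, so leaving out a replicate gave no value for it. Start site shares and the 12 gene lists were not run, since gene positions in mm9 were not used here. No paired analysis was possible because the GFP-3Flag and mock samples that share the replicate numbers were not analysed here. Depth is unknown.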

Other observations

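Of the tests in this part, those on chromosome 14 and on the k-mers were chosen only after the results were seen, and the k-mer cores were too. The event densities behind the test on chromosome X were also added after seeing the data. Less frequent k-mers of replicate 2 held cores known from other promoter-binding factors. The core ATGGCGG, part of the element bound by YY1, lay in 4 k-mers assigned to 247 events, with a median fold of 5.3. The core GGCGCAT, which overlaps the palindrome bound by NRF1, lay in 4 k-mers at 144 events, with a median fold of 4.7. The median fold of the whole list of replicate 2 was 5.3. Neither core lay in any k-mer of replicate 1, whose k-mers of 7 bases would have to equal it. Events on chromosome X carried a k-mer more often than the list as a whole, at 95% in replicate 1 and 85.5% in replicate 2. The k-mers do not show which protein was bound, and no test of these cores was run.

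Events with many control reads were frequent at the top of the lists. Of the 20 events with the most IP reads, 9 in replicate 1 and 11 in replicate 2 were above the 99th percentile of control reads of their list, which was 10.1 and 51.9 reads. Events above it had a median fold of 11.3 in replicate 1, against 18.3 for the rest, and 5.1 against 5.3 in replicate 2.

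The paired events at positions 13177392 and 13177048 of chromosome 14 exceeded every other event in IP minus control reads in both replicates. The Fezf2 gene itself is on chromosome 14, and the gene at this position was not looked up in mm9. One hypothesis is that reads from the infected Fezf2 construct align to the exons of the gene, and another is binding of the tagged protein at this locus. Copies of a construct can differ between infections, so its ratio of replicate 2 to replicate 1 may stand apart; the ratios were 3.98 and 2.46, within the central 95% of other pairs (0.73 to 4.75) but above their upper quartile of 2.41. The explanations cannot be told apart from these values, since neither reads across exon junctions nor a control list were used here.

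The leading k-mers differed between the replicates, with CCGCCGC first in replicate 1 and GGCGGGGC in replicate 2. The leading k-mers were not confined to sites of 1 list, and were not rarer at sites near an event of the other list. Stronger events had a partner more often, and strength was not held fixed. The comparison therefore does not settle whether different sites in each list contribute. Among events with a k-mer, CCGCCGC made up 25.4% of those with a partner within 500 bp and 14.7% of those without in replicate 1 (ratio 1.73, 95% interval 1.63 to 1.83), and GGCGGGGC made up 24.0% and 9.10% in replicate 2 (ratio 2.63, 2.24 to 3.10). Each list had its own set of k-mers, of 7 bases in replicate 1 and 8 in replicate 2, so the leading k-mers could not be identical. How far the separate sets account for the difference in sequence stays open. The k-mers matched at 15.5% of paired events, but at most 22.0% could have matched under any pairing of these k-mers. The match therefore does not settle it. No biological explanation was tested, since both lists belong to 1 group.

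Chromosome X had few events per Mb in both replicates. Lower read coverage of X could remove weak events: control reads at its events were 0.63 of the autosomal median in replicate 1 and 0.68 in replicate 2. With autosomal IP reads scaled down by these factors and the minimum of each list applied again, the density of X stood at 0.558 of the lowest autosome in replicate 1 and 0.464 in replicate 2, with its upper 95% limit below that autosome in both. Scaling of this size, with the IP minimum alone, thus did not bring the autosomes down to X. The factors came only from listed events, so sites on X lost to low coverage did not enter them. The significance threshold was not applied again. Lower coverage as the whole cause is therefore not settled. A lower density of bindable promoters or of uniquely alignable sequence on X stays open too. No biological explanation was tested.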
